A study of Caenorhabditis elegans with 2 samples.

How the data were processed

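Whole young adult worms of 1 strain, whose hsf-1 gene carries a fluorescent protein and epitope tags, were profiled in 2 biological replicates, per the labels. Chromatin was fragmented by sonication and precipitated with an antibody against green fluorescent protein, per the labels. The authors deposited 4 thresholded and 4 ranked peak lists on ce11, as the deposited file listings state. Each replicate has lists made from its own alignments, and the pooled and conservative lists were made from the alignments of both replicates, per the same listings. A further parent is shared by all of them and by the deposited signal over control. Its type is not stated, and it is taken here to be the control. No control sample and no signal track was analysed here. The aligner, the peak caller and their versions are not given in the sources used here, nor is the number of reads, so the depth is unknown and the intervals given cover the counting of peaks or genes only.

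Several kinds of values were used. The signal of each peak, which the authors deposited, is the peak caller's value and is not scaled between lists. The score, which the authors deposited, is the irreproducible discovery rate (IDR) of the peak rescaled to whole numbers: it matched 125 times the negative log2 of the IDR, capped at 1000, within 1 for 100% of the ranked peaks. The ranked lists give the −log10 of the IDR of each peak, as deposited by the authors. IDR measures how well the rank of a peak agrees between 2 sets of peaks. Tested on the values, every thresholded list held only ranked peaks with an IDR of 0.01 or less. Of the 97869 ranked peaks of the pooled analysis, 3079 passed that IDR and 2935 are in the thresholded list. The 144 others are absent from it, and the listings name 1 further parent file for the thresholded lists without saying what it holds. The pooled list has 19 intervals that repeat with another summit, and each summit was counted. There were 16 columns of values from single peak sets in the ranked series tables whose sample is not named, and these were not used. Values per replicate at a pooled peak come instead from each replicate's own ranked list, by overlap of at least 1 bp and the nearest summit.

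Positions were annotated with Ensembl release 115 genes on the same assembly, and sequence and repeat masking were taken from the reference genome. A promoter window ran from 1000 bp upstream to 200 bp downstream of every annotated transcript start of the 19973 protein-coding genes on the nuclear chromosomes. A gene was called bound when a pooled summit lay in its window, so that divergent genes can share a peak. The heat shock element was GAANNTTCNNGAA or TTCNNGAANNTTC without mismatch within 100 bp of the summit, and the control pattern was GAANNNTTCNNNGAA or TTCNNNGAANNNTTC. Its background was 10 windows per peak, placed from the transcript starts of unbound genes at the distance of the summit from its own nearest start. Windows for summits far from a start thus lie outside promoters, and the windows were not matched on masking. Shares carry 95% Wilson intervals. Odds ratios carry 95% Woolf intervals, with a continuity correction where a cell was 0. Random placements kept each peak on its chromosome, 1000 times (100 times for the annotation of locations), and did not avoid masked or unmappable sequence. A summit was called masked when at least 50% of its window was soft-masked in the reference.

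The 23 gene lists, the main tests, the alternatives and the rule for naming genes were fixed before the data were examined. The splits of peaks by signal rank, by number of elements and by presence in the replicate lists were not in that plan. Nor were the genomic clusters of elements, the correlation of element number with signal and the annotation of locations. The rule named the 10 strongest pooled peaks with their genes, hsf-1, every heat-inducible heat shock protein gene, the 3 members with the strongest peak in each other list that passed its test, and the 3 strongest peaks in each replicate list that did not overlap the other. There were 3 list members without a match in the annotation. Gene lists were tested with two-sided Fisher's exact tests, chromosomes with exact binomial tests against the share of protein-coding genes, and noncoding classes and overlaps with one-sided permutation tests, with Benjamini-Hochberg adjustment within each family at 0.05. The alternatives were other overlap rules, the conservative list, the stronger part of the pooled list by signal, each replicate list alone, other promoter windows, other assignments of genes, other motif windows and backgrounds, and base pairs as the chromosome reference. A pair of further alternatives was chosen after the data were seen.

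The computations used Python with numpy, pandas and scipy. The statistics were tested on simulated data. With 1000 of the 2935 peaks planted at transcript starts, the promoter share found was 50.7% against 51.8% planted. All 398 planted elements were found. A list of 25 genes with 10 bound among 19973 was called in 100 of 100 runs, in which 4 of 2200 unplanted lists were called. Of the overlap planted at 59.0%, 61.4% was found.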

Results

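The binding of HSF-1, the conserved transcription factor of the heat shock response, was profiled by chromatin immunoprecipitation and sequencing in whole young adult Caenorhabditis elegans. The worms carried an HSF-1 fusion with enhanced green fluorescent protein, inserted at the hsf-1 locus by genome editing, and the fusion was precipitated with an antibody against green fluorescent protein. There were 2 biological replicates of 1 group, young adults of 63 h grown from larvae synchronised by starvation, and the labels name no heat treatment. The thresholded peak lists held 1217 peaks in replicate 1 and 1877 in replicate 2. The pooled list held 2935 peaks and a conservative list of both replicates held 2572. The number of reads behind each list is not given in the sources used here, and without a second group no difference between conditions could be tested. Signal is the peak caller's own value for each peak, and it is used here to rank and describe peaks within a list. Positions are 1-based on ce11.

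The replicates shared most of their strong peaks. In replicate 1, 1037 of the 1217 peaks overlapped a peak of replicate 2 by at least 1 bp, a share of 85.2% (95% Wilson interval 83.1 to 87.1). In replicate 2, 1007 of the 1877 peaks overlapped a peak of replicate 1, which was 53.6% (51.4 to 55.9). Random placement of the same peaks on the same chromosomes gave 1.09% and 0.684% on average, and neither observed share was reached in 1000 placements (one-sided permutation p = 0.001 for each, the smallest the placements can give). Peaks found in replicate 2 alone had a median signal of 55.9 against 109.0 for shared peaks. When both lists were cut to the shorter length, the share of replicate 2 peaks found in replicate 1 was 73.2%. Across the 992 peaks paired between the lists, the log2 signals had a Pearson r of 0.907 and a Spearman rho of 0.845 (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). These correlations are across peaks, which are not independent replicates. Of the 2935 pooled peaks, 1012 (34.5%) were in both replicate lists and 1061 (36.1%) were in neither. The latter had a heat shock element in 4.52% of cases against 33.4% for peaks in both lists, and lay in coding exons in 31.5% against 6.52%.

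**Figure D1:**
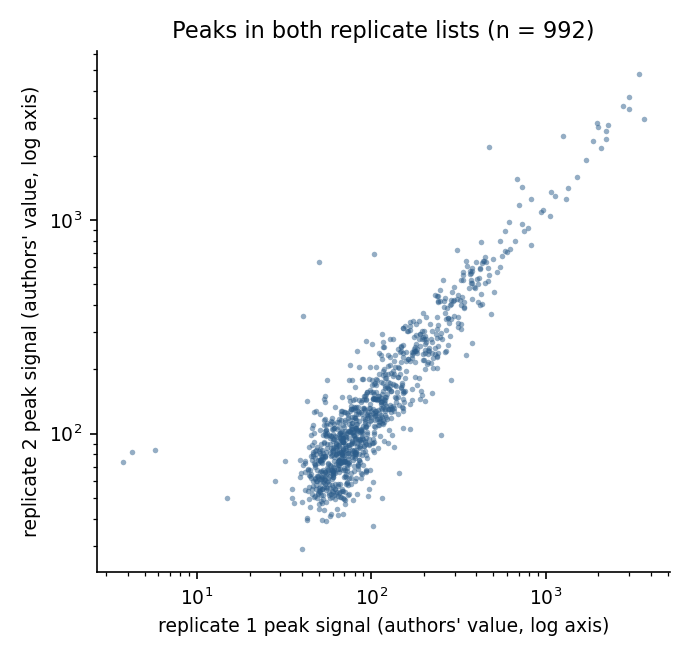
Peak signal in replicate 1 (x axis) against replicate 2 (y axis), both log axes, in the units of the authors' peak caller, with 1 point for each of the 992 peaks paired between the replicate lists. The points follow a diagonal band, with a Pearson r of 0.907 on the log2 scale.

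Among peaks that did not overlap the other replicate's list, the 3 strongest of replicate 1 lay in an intron near glb-33 (chromosome V, 1352441 to 1352617, signal 165.3), in an intron near snt-5 (chromosome V, 1403526 to 1403835, signal 153.1) and 32 bp upstream of vps-51 (chromosome I, 5807202 to 5807387, signal 134.3). The 3 strongest of replicate 2 were intergenic. They lay nearest to tgn-38 (chromosome IV, 12022533 to 12022756, signal 450.01), M03A1.3 (chromosome II, 4554550 to 4554707, signal 246.7) and ZK1086.2 (chromosome X, 13795114 to 13795302, signal 167.5). These 6 peaks held between 1 and 27 heat shock elements within 100 bp of their summits. The peak near tgn-38 overlapped a peak of signal 342.8 in the ranked list of replicate 1, and none of the other 5 had a match in the other replicate's ranked list. The tgn-38 peak lay in a region (chromosome IV, 12022516 to 12025626) where 2 pooled peaks, of at most 798.3 in signal, passed the IDR but are absent from the thresholded list. Over all peaks that did not overlap the other list, most had a match in its ranked list, 158 of 180 (87.8%) of replicate 1 and 794 of 870 (91.3%) of replicate 2.

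Of the 10 strongest pooled peaks, 3 lay in promoters of chaperone genes, 6 in intergenic runs of heat shock elements and 1 at a metabolic gene. The chaperone peaks lay between the divergent HSP70 family genes F44E5.4 and F44E5.5, at dnj-13, which encodes an HSP40 cochaperone, and between hsp-110, an HSP110 cochaperone gene, and rpn-3, a proteasome subunit gene. The peak at F44E5.4 and F44E5.5 (chromosome II, 11759232 to 11759743, intergenic) had a signal of 6602 in the pooled list, 3640 in replicate 1 and 2970 in replicate 2, and its summit lay 158 bp upstream of F44E5.4 and 193 bp upstream of F44E5.5. The dnj-13 peak (chromosome II, 11545279 to 11545723) had a signal of 6173, with 2754 and 3408 in the replicates. Its summit lay 202 bp upstream of dnj-13, in an annotated intron, and 671 bp upstream of F54D5.9. The peak between rpn-3 and hsp-110 (chromosome III, 8446886 to 8447326, intergenic) had a signal of 4697, with 1992 and 2720 in the replicates, and lay 195 bp and 249 bp upstream of their starts.

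A further top peak lay in an untranslated region of pck-2, a phosphoenolpyruvate carboxykinase gene, 27 bp downstream of an annotated transcript start (chromosome I, 7868913 to 7869589, signal 4690), and held 21 elements. The other 6 of the 10 were intergenic and outside every promoter window, and each held between 15 and 24 elements within 100 bp of its summit. The strongest of all lay nearest to srv-14, 1846 bp upstream (chromosome IV, 15895839 to 15896260), with a signal of 8245 in the pooled list, 3434 in replicate 1 and 4788 in replicate 2. The next was nearest to fbxa-190 (chromosome X, 1375010 to 1375479, signal 6784). The remaining 4 were nearest to Y41E3.13 (chromosome IV, 15059067 to 15059863, signal 6389), Y102A11A.1 (chromosome X, 2057773 to 2058478, signal 5204), VY10G11R.1 (chromosome IV, 16458440 to 16458687, signal 4720) and Y105E8B.9 (chromosome I, 14686395 to 14686844, signal 4602). All 10 peaks were in both replicate lists.

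**Figure D2:**
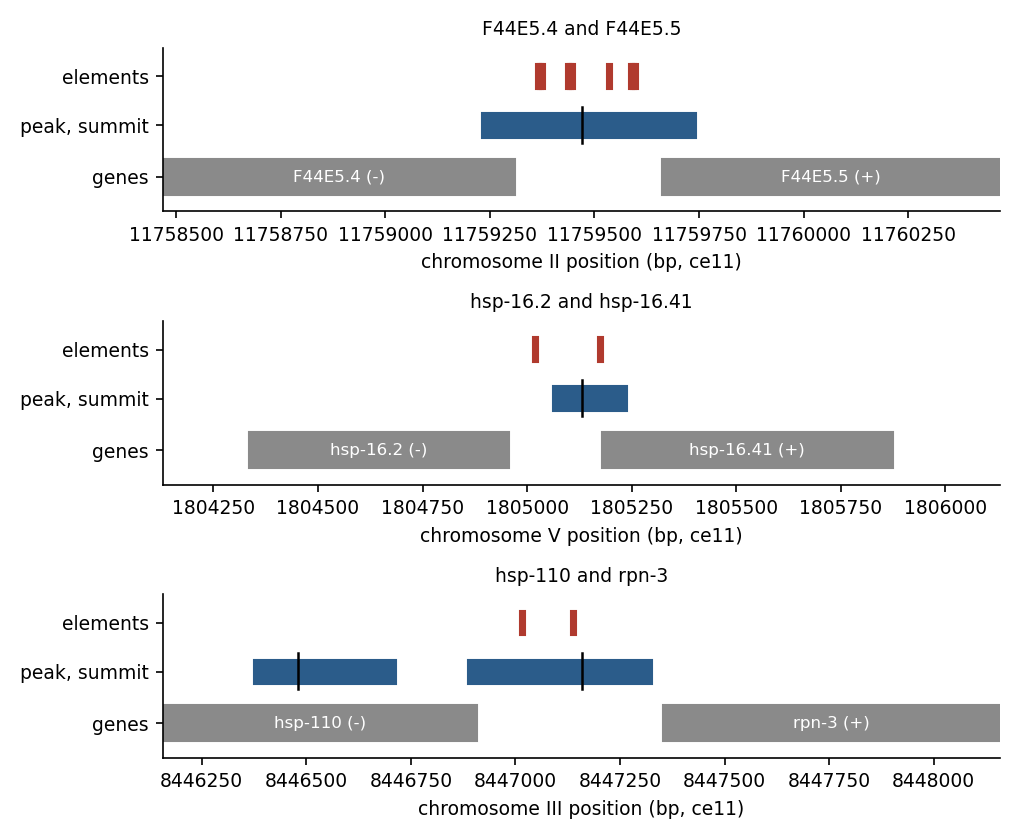
Maps of 3 promoter regions on ce11, drawn to scale, with position in bp on the x axis. Grey boxes are genes with their strand, blue boxes are pooled peaks with the summit as a black line, and red boxes are perfect heat shock elements. The summits at F44E5.4 and F44E5.5, at hsp-16.2 and hsp-16.41 and at hsp-110 and rpn-3 lie between the divergent genes, within 100 bp of an element. A further, separate peak lies inside hsp-110.

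Heat shock elements, the inverted GAA repeats that HSF proteins bind, marked the strongest peaks. A perfect element (GAANNTTCNNGAA or TTCNNGAANNTTC) lay within 100 bp of 488 of the 2935 pooled summits, which was 16.6% (Wilson interval 15.3 to 18). In windows matched on the distance to the transcript starts of unbound genes, but not on masking, the share was 1.21% of 29350 (odds ratio 16.3, 95% interval 14.1 to 18.8, two-sided Fisher's exact p = 1.02e-290). In windows 1000 bp to either side of the same summits it was 3.02%. The share was 29.6% in the list of replicate 1 and 23.9% in that of replicate 2. A control pattern with the same letters and a changed spacing was found at 0.716% of pooled summits and 0.763% of matched windows (odds ratio 0.937, 95% interval 0.598 to 1.47, exact p = 0.911). The element was present at 78 of the 100 strongest peaks, at 70 of the next 100, at 42.5% of peaks ranked 201 to 400 and at 3.91% of peaks ranked 2501 to 2935. Without the peaks that held 6 or more elements, an alternative chosen after the data were seen, the share over the pooled list was 7.73% against 1.33% in matched windows, and 37 of the 100 strongest peaks had an element. With 1 mismatch allowed it was 29.4% against 17%.

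**Figure D3:**
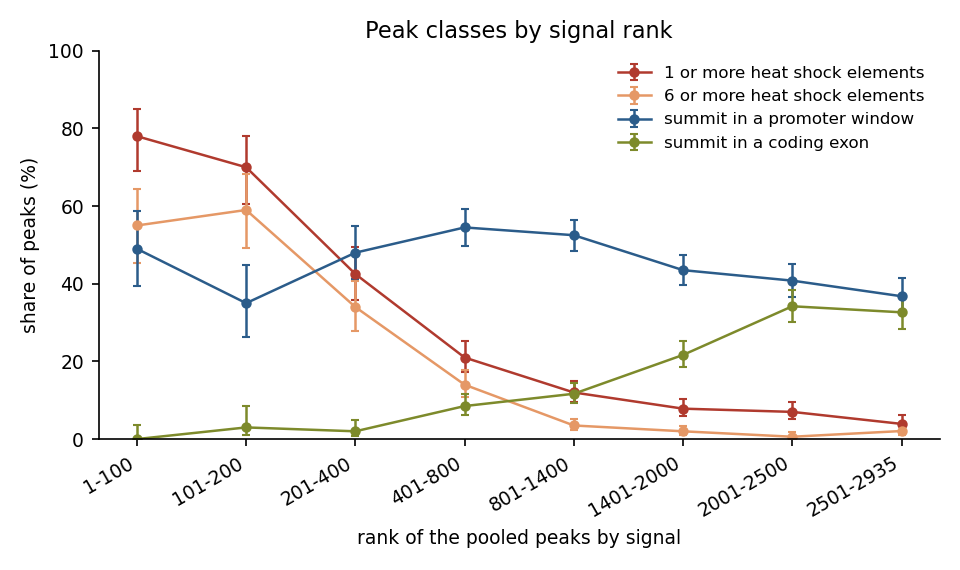
Share of pooled peaks (y axis, percent) in 8 bins of signal rank (x axis, strongest at the left) with at least 1 heat shock element, with 6 or more, with the summit in a promoter window and with the summit in a coding exon. Bars are 95% Wilson intervals. The element share fell from 78% to 3.91% while the coding exon share rose from 0% to 32.6%.

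Runs of many elements carried a large part of the strong signal. Elements in such runs overlap, and each start position was counted. The comparisons by number of elements in this paragraph and the next were not in the plan fixed before the data were examined. There were 283 pooled peaks with 6 or more elements within 100 bp of the summit, and only 11.7% of them lay in a promoter window, against 49.4% of the 2447 peaks without an element. Of the 283, 180 were intergenic and 97 were intronic, and the whole set lay in sequence that the reference assembly masks as repetitive. The replicate lists held 251 of them in replicate 1 and 272 in replicate 2. Median signal was 166.9 with 6 to 11 elements, 392.3 with 12 to 17 and 671.1 with 18 or more, against 87.3 without an element, 130.5 with 1 and 101.0 with 2 to 5. Among the 283 peaks the number of elements and the signal had a Spearman rho of 0.675 (two-sided permutation p = 1e-05, across peaks).

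The same relation was seen from the genome outward. The 6 nuclear chromosomes held 16904 perfect elements, which formed 7565 clusters when elements within 100 bp were joined. Each cluster or isolated element was extended by 100 bp on each side, and it counted as overlapped when a pooled peak touched the extended interval. Larger clusters span more sequence and so offer a longer target, which was not corrected for. With these extensions, a pooled peak overlapped 262 of the 347 clusters with 6 or more elements, which was 75.5% (70.7 to 79.7). It overlapped only 196 of the 6441 isolated elements, or 3.04% (2.65 to 3.49). Isolated elements in promoter windows were overlapped in 6.16% of cases (5.08 to 7.44) and those elsewhere in 2.01% (1.65 to 2.44). Large clusters were overlapped in 88.6% of cases in promoter windows (31 of 35) and in 74.0% elsewhere (231 of 312).

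**Figure D4:**
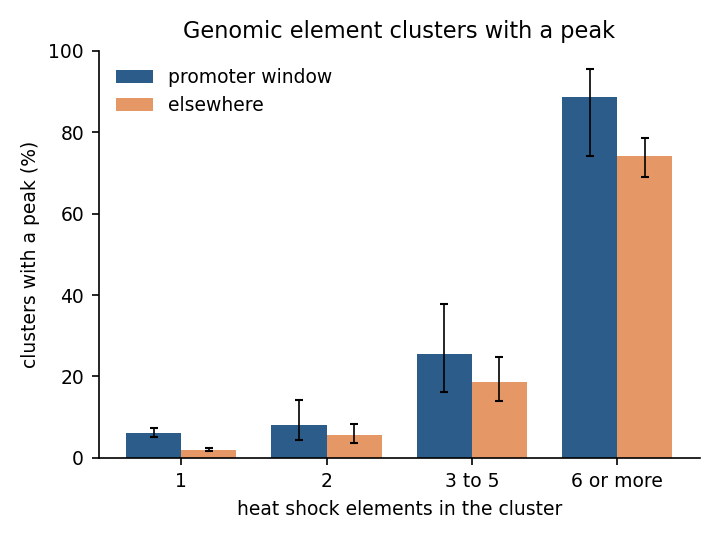
Share of genomic clusters of perfect heat shock elements that overlapped a pooled peak (y axis, percent), by the number of elements in the cluster (x axis), for clusters in promoter windows (blue) and elsewhere (orange). Each cluster was extended by 100 bp on each side before overlap was counted. Bars are 95% Wilson intervals. The share rose from 6.16% and 2.01% for isolated elements to 88.6% and 74.0% for clusters of 6 or more.

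Peaks were concentrated at promoters. Of the 2935 summits, 1338 lay from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, which was 45.6% (43.8 to 47.4). Random placement gave 26.5% on average and at most 28.9% in 1000 placements (one-sided permutation p = 0.001, the smallest the placements can give). These summits marked 1524 of the 19973 protein-coding genes, or 7.63%. By annotation, 52.6% of all summits were intergenic (random 36.0%), 20.9% lay in introns (34.1%), 18.9% in coding exons (24.9%) and 7.63% in untranslated regions (4.90%). Coding exons held none of the 100 strongest summits and 32.6% of those ranked 2501 to 2935.

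Genes for cytosolic chaperones were among the most often bound. Of 17 genes for cytosolic chaperones and cochaperones, 13 had a promoter peak (76.5%, against 7.57% of other genes, odds ratio 39.7, exact adjusted p = 2.90e-11), with a median signal of 1066. Lists were tested with two-sided Fisher's exact tests adjusted over 23 lists by Benjamini-Hochberg. Beyond dnj-13 and hsp-110, the next strongest member was hsp-1, the constitutive HSP70 gene (chromosome IV, 17278216 to 17278946, intergenic, 388 bp upstream), with a signal of 4387 in the pooled list, 2076 in replicate 1 and 2161 in replicate 2. Of the 14 genes for the cytosolic chaperonin and prefoldin, which fold actin and tubulin, 11 were bound (78.6%, odds ratio 44.7, exact adjusted p = 6.66e-10). The strongest were cct-8 (chromosome IV, 1094217 to 1094466, signal 1113), cct-5 (chromosome III, 4508454 to 4508692, signal 970.8) and cct-7 (chromosome V, 1871910 to 1872099, signal 373.3). The summits of these peaks also lay in the promoter windows of Y55F3AR.2, F25F2.1 and T10B5.4, in that order. With only the nearest gene counted for each summit, both calls were kept at lower shares, 47.1% of the chaperone genes and 28.6% of the chaperonin and prefoldin genes. No perfect element lay within 100 bp of the strongest peak of any of these 11 genes, and 5 of the 13 bound chaperone genes had one. In a count chosen after the data were seen, an element with at most 1 mismatch lay within 100 bp of 7 of the 11 chaperonin and prefoldin peaks and 15 of the 18 chaperone peaks, against 15.5% of matched windows at unbound promoters. It lay at 3 of 37 ribosomal, 1 of 17 germ granule and oocyte and 0 of 14 DNA replication peaks.

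Of the 11 annotated genes in the list of heat-inducible heat shock proteins, 6 were bound (54.5%, odds ratio 14.6, exact adjusted p = 0.000165), and 36.4% with only the nearest gene counted for each summit. Besides F44E5.4 and F44E5.5 these were the divergent small heat shock protein genes hsp-16.2 and hsp-16.41, hsp-70 and F08H9.3. The peak between hsp-16.2 and hsp-16.41 (chromosome V, 1805063 to 1805239, intergenic) had a signal of 358.9, with 191.2 and 158.6 in the replicates, and lay 173 bp and 48 bp upstream of their starts. The hsp-70 peak (chromosome I, 9322534 to 9322675, in an annotated intron, 92 bp upstream) had a signal of 278.6, with 137.4 and 148.1. The F08H9.3 peak (chromosome V, 14463168 to 14463471, in an untranslated region) had a signal of 101.3 and was in the list of replicate 2 but not of replicate 1. It held no perfect element and also overlapped the snRNA gene F08H9.10 (14463188 to 14463352), so which gene it belongs to is uncertain. The window of F08H9.4 held ranked peaks of at most 42.8 in signal, at an IDR of 0.127. The windows of the duplicated genes hsp-16.1 and hsp-16.48 on chromosome V, a name each for 2 loci between 9087293 and 9090604, held no peak in the ranked list. These copies are nearly identical in sequence, so reads from them may not have been placed, and their values are uncertain. Of the 8 other small heat shock protein genes 1 was bound (exact adjusted p = 0.569), the embryonic sip-1, named after its value was seen. Its peak had a signal of 104.4 in replicate 1 and 6.46 in replicate 2, and none of the 8 was bound in the list of replicate 2 alone.

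Other protein quality control lists were bound more often than other genes, with lower median signals than the chaperone list. Of 14 mitochondrial quality control genes, 7 were bound (odds ratio 12, exact adjusted p = 9.08e-05), led by the mitochondrial chaperonin gene hsp-60 (chromosome III, 1618870 to 1619280, 647 bp upstream, signal 2560), the mitochondrial HSP70 gene hsp-6 (chromosome V, 4827013 to 4827215, signal 345.5) and the protease gene clpp-1 (chromosome II, 10301004 to 10301307, intron, signal 102.2). Of 31 proteasome genes, 6 were bound (odds ratio 2.91, exact adjusted p = 0.0397), led by rpn-3, rpn-2 (chromosome III, 6198434 to 6198754, signal 1049) and rpn-9 (chromosome II, 11239011 to 11239314, signal 164.6). Of 25 genes for ubiquitin and its conjugating enzymes, 6 were bound (odds ratio 3.83, exact adjusted p = 0.0173), led by the polyubiquitin gene ubq-1 (chromosome III, 5939151 to 5939419, signal 1071), uba-1 (chromosome IV, 9995007 to 9995298, signal 748.1) and ubc-9 (chromosome IV, 4650604 to 4650938, signal 546.7). Of 19 genes for protein folding in the endoplasmic reticulum and the unfolded protein response, 5 were bound (odds ratio 4.33, exact adjusted p = 0.0199). They were pek-1 (chromosome X, 11414979 to 11415120, signal 273.9), hsp-4 (chromosome II, 7352579 to 7352882, signal 97.4), crt-1 (chromosome V, 6100665 to 6100968, signal 93.4) and, named after their values were seen, pdi-3 and hsp-3. Of 25 autophagy genes, 6 were bound (odds ratio 3.83, exact adjusted p = 0.0173), led by atg-7 (chromosome IV, 11080812 to 11081115, coding exon, signal 103.0), epg-4 (chromosome III, 7181873 to 7182176, signal 98) and lgg-1 (chromosome II, 6348488 to 6348791, signal 96.3). The listed peaks at hsp-60, hsp-6, clpp-1, rpn-2 and rpn-9 also lay in the promoter window of another gene. These genes were Y22D7AL.10, C37H5.5, mdt-22, C23G10.7 and T06D8.9, in that order. The listed peaks at atg-7, lgg-1 and crt-1 were in neither replicate list, those at epg-4 and clpp-1 were in that of replicate 1 alone and that at hsp-4 in that of replicate 2 alone. The autophagy call was lost with either replicate alone (4% bound in each, exact adjusted p = 1 for replicate 2 and 0.651 for replicate 1). The endoplasmic reticulum call was lost in replicate 1 alone (5.26%, exact adjusted p = 0.634) and the mitochondrial call in replicate 2 alone (14.3%, exact adjusted p = 0.257). In peaks of both replicate lists, an alternative chosen after the data were seen, the autophagy call (0%), the endoplasmic reticulum call (5.26%, exact adjusted p = 0.605) and the mitochondrial call (14.3%, exact adjusted p = 0.126) were lost. The proteasome call was lost in the conservative list (16%, exact adjusted p = 0.0889), in the stronger part of the pooled list (12.9%, exact adjusted p = 0.0963), with a window of 500 bp upstream (12.9%, exact adjusted p = 0.132) and with only the nearest gene counted (16%, exact adjusted p = 0.0536).

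Genes of the translation machinery, DNA replication and the germline formed the other large group. Of 80 cytosolic ribosomal protein genes, 37 were bound (46.3%, odds ratio 10.7, exact adjusted p = 1.16e-19), led by rpl-3 (chromosome III, 3867451 to 3867695, signal 878.8), rpl-20 (chromosome IV, 4749961 to 4750187, signal 724.4) and rpl-15 (chromosome IV, 654828 to 655021, signal 476.8). Of 40 translation factor genes, 10 were bound (odds ratio 4.06, exact adjusted p = 0.00152), led by eef-2 (chromosome I, 9163445 to 9163579, signal 215.3), eif-3.C (chromosome I, 9979737 to 9980040, signal 203.3) and eef-1G (chromosome V, 10965528 to 10965831, signal 152.0). Of 29 DNA replication genes, 14 were bound (odds ratio 11.4, exact adjusted p = 2.13e-08), led by the sliding clamp gene pcn-1 (chromosome IV, 4049615 to 4049766, signal 323.5) and the replicative helicase genes mcm-2 (chromosome II, 12006812 to 12006920, signal 252.3) and mcm-3 (chromosome V, 15059668 to 15059797, signal 249.1). Of 25 germ granule and oocyte genes, 17 were bound (68%, odds ratio 26.0, exact adjusted p = 4.26e-13), led by cbd-1 (chromosome IV, 11372688 to 11372952, signal 1041), mex-5 (chromosome IV, 13353337 to 13353545, signal 631.9) and the germline helicase gene glh-1 (chromosome I, 6854354 to 6854528, signal 305.6). Of 28 meiosis genes, 8 were bound (odds ratio 4.86, exact adjusted p = 0.00184), led by the cohesin genes rec-8, which shares its peak with mex-5, and coh-3 (chromosome V, 14457158 to 14457362, signal 445.1), and the synaptonemal complex gene syp-4 (chromosome I, 6847170 to 6847473, signal 169.1). The syp-4 peak also overlapped the snRNA gene H27M09.6. Several of these peaks also lay in the promoter window of another protein-coding gene. They were those at rpl-20 (Y17G9B.5), rpl-15 (K11H12.8), eef-2 (clsp-1), eef-1G (ctf-4), mcm-3 (C25D7.15), coh-3 (bmk-1) and syp-4 (H27M09.5). The meiosis call was lost in replicate 2 alone (14.3%, exact adjusted p = 0.103) and kept in replicate 1 alone at 17.9%. The other 4 calls were kept with either replicate alone, at lower shares. The ribosomal share was 27.5% in replicate 1 alone, the germ granule and oocyte share 44% in replicate 2 alone, and the translation factor share 12.5% in replicate 1 and 15% in replicate 2. With only the nearest gene counted for each summit, the DNA replication share was 31.0%. In these 5 lists none of the strongest peaks of bound genes had a perfect heat shock element within 100 bp.

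Of 72 histone genes, 19 were bound (odds ratio 4.38, exact adjusted p = 4.05e-06). The strongest were his-39 and his-6, which share a peak with 6 elements (chromosome V, 8535883 to 8536010, signal 256.9), and his-67 (chromosome I, 9988925 to 9989084, signal 218.8). The his-67 peak also lay in the promoter windows of his-68 and alg-5. Histone genes lie close together, and with only the nearest gene counted for each summit the share was 6.94% and the call was lost (exact adjusted p = 0.706). In replicate 1 alone the share was 12.5% and the call was kept.

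Chemoreceptor genes, which act in sensory neurons, were rarely bound. Of 1308 chemoreceptor genes, 17 were bound (1.30%, against 8.07% of other genes, odds ratio 0.150, exact adjusted p = 2.57e-25), and the strongest were str-138 (chromosome V, 8057787 to 8058090, signal 221.7), srw-10 (chromosome III, 12754947 to 12755027, signal 210.1) and srw-77 (chromosome V, 16643874 to 16644177, signal 167.0). The chemoreceptor share was 0.765% in replicate 2 alone and 0.459% in replicate 1 alone, and the call was kept in both. None of 55 sperm protein genes was bound (0%, Wilson upper limit 6.53%, exact adjusted p = 0.0317). The sperm call was lost in each replicate list (exact adjusted p = 0.196 for replicate 2 and 0.372 for replicate 1). The other tissue lists did not differ from other genes past the threshold. They were the intestine with 0 of 15 bound (exact adjusted p = 0.715), muscle with 1 of 25 (exact adjusted p = 1), neurons with 1 of 21 (exact adjusted p = 1) and cuticle collagens with 7 of 173 (exact adjusted p = 0.112). The bound muscle gene was the actin gene act-2 (signal 1196) and the bound neuronal gene was unc-31 (signal 259.1), both named after their values were seen. The unc-31 peak also overlapped the snRNA gene ZK897.3. Of 19 redox and detoxification genes, 2 were bound (exact adjusted p = 0.715), gst-1 and prdx-2.

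**Figure D5:**
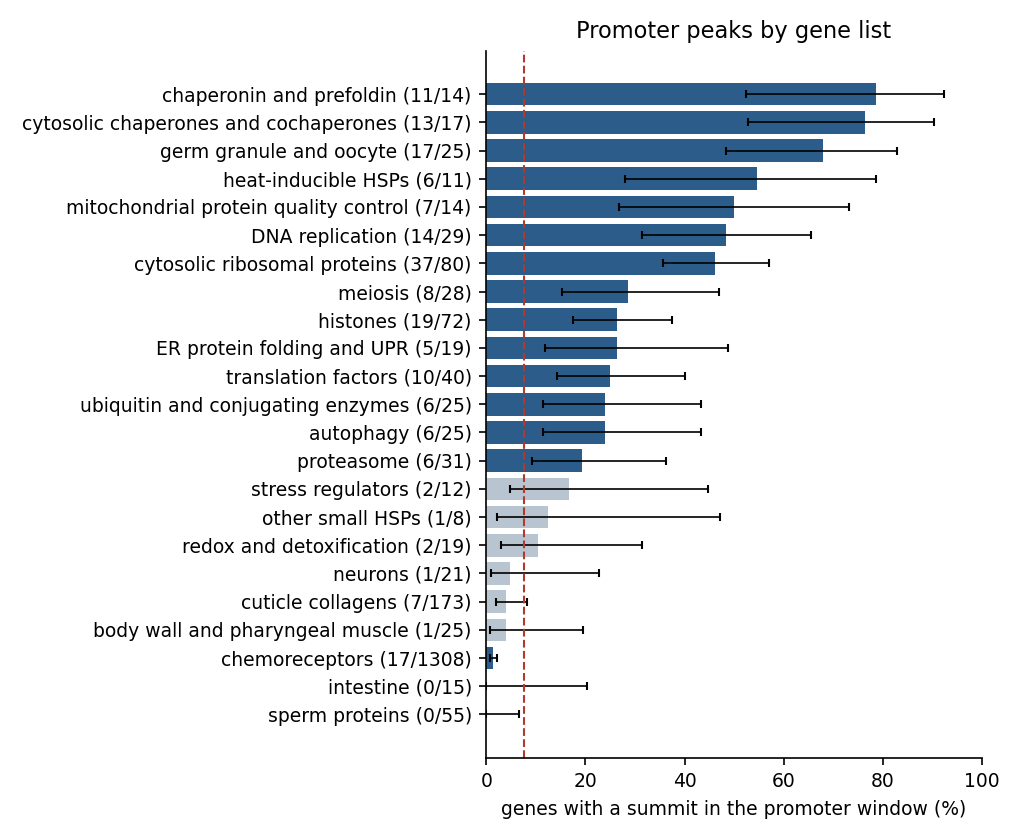
Share of the genes of each fixed list with a summit in the promoter window (x axis, percent), with the bound and total numbers beside each name. Dark bars passed the adjusted Fisher's exact test, light bars did not, the error bars are 95% Wilson intervals and the dashed line marks the 7.63% of all protein-coding genes. The chaperonin and prefoldin list (78.6%) and the cytosolic chaperone list (76.5%) stand highest.

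The hsf-1 gene itself (chromosome I, 11953507 to 11963085, minus strand) had no peak in its promoter window, in the pooled list or in the ranked list. A pooled peak lay 562 bp beyond its 3′ end (11952793 to 11953096, signal 95.8), in an untranslated region of the neighbouring gene R06C1.6, and it was in the list of replicate 2 but not of replicate 1. Of the 12 stress regulators, 2 were bound (exact adjusted p = 0.296). These were hsb-1, which encodes an HSF binding protein (signal 528.7), and sir-2.1 (signal 83.6), both named after their values were seen. With each replicate list alone, 1 of the 12 was bound.

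Peaks were sparse on the X chromosome. It held 240 of the 2935 peaks, or 8.18% (7.24 to 9.22), against 13.7% of protein-coding genes (exact binomial test, two-sided, adjusted p = 8.53e-20, adjusted over 6 chromosomes). Chromosome V also held fewer peaks than its genes, 18.5% against 25% (exact adjusted p = 1.59e-16). Chromosome III held more, 19.3% against 13.2% (exact adjusted p = 8.53e-20), as did chromosome I, 18.6% against 14.4% (exact adjusted p = 9.16e-10), and chromosome IV, 19.4% against 16% (exact adjusted p = 2.71e-05). The share of chromosome II was 16% against 17.3% (exact adjusted p = 0.0746), and in the list of replicate 2 alone it was 15.2% and passed the test (exact adjusted p = 0.0172). Neighbouring peaks are not independent of each other, so these p-values are too small.

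Several classes of short noncoding genes had nearby summits more often than random placement gave. A summit lay within 200 bp of 147 of 612 tRNA genes (24.0%, random 1.13%), 96 of 346 snoRNA genes (27.7%, random 1.70%), 32 of 99 snRNA genes (32.3%, random 1.63%) and 13 of 30 spliced leader RNA genes (43.3%, random 1.64%). For each of these 4 classes no placement of 1000 reached the observed share (one-sided permutation, adjusted p = 0.002). These shares were lower in replicate 1 alone, at 5.56% for tRNA, 13.6% for snoRNA and 18.2% for snRNA genes, and these calls were kept. The tRNA share in peaks of both replicate lists, an alternative chosen after the data were seen, was 3.76%. The microRNA share was 4.6% (12 of 261, random 1.42%, permutation adjusted p = 0.0048) and the lincRNA share 7.73% (15 of 194, random 4.64%, adjusted p = 0.0427). In the list of replicate 1 alone both calls were lost (microRNA 1.53%, lincRNA 3.61%, permutation adjusted p = 0.1 for each). The lincRNA call was also lost in the conservative list (6.70%, permutation adjusted p = 0.06) and, in alternatives chosen after the data were seen, without arrays (7.22%, permutation adjusted p = 0.0613) and in peaks of both lists (3.61%, permutation adjusted p = 0.052). piRNA genes (0.280% of 15363, random 1.36%) and rRNA genes (0 of 20) were not above random placement in this one-sided test. A peak overlapping 1 of the tandem rRNA genes named rrn-4.2 (chromosome V, 17122046 to 17122349, signal 276.9), named after its value was seen, passed the IDR threshold but is absent from the thresholded list. The median signal at bound tRNA genes was 90.8 and at bound snoRNA genes 105.6, and 1 gene of each of these classes had a perfect heat shock element within 100 bp of its summit.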

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

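The tests of copy number, of changed elements at chaperone genes, of tissue lists and of weak peaks were chosen after the results they bear on had been seen. The other tests below were written down before they were run, but the patterns they bear on came from these same data.

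Strong peaks exist outside the thresholded list. In the pooled ranked list, 144 peaks passed an IDR of 0.01 and are absent from the thresholded list, and the strongest had a signal of 7450, which would rank it second in the pooled list. It lay in a block of 14 such peaks on chromosome V from 7913181 to 7924797, where srsx-7 is the gene nearest to that strongest peak, and all 14 held a perfect heat shock element. No thresholded peak lay in that block. In all, 25 of the 144 held an element (17.4%, Wilson interval 12 to 24.4) and 89.6% lay in masked sequence, against 23.5% of the pooled peaks. They were picked out because they carry signal in data that the comparisons above do not use.

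Runs of heat shock elements gave many of the strongest peaks, mostly outside promoters and in masked sequence. Masked windows of 200 bp without an element rarely held a summit, 0.280% of 127998 against 45.9% of 560 masked windows with 6 or more elements. This was 0.00611 times the rate (95% interval 0.00533 to 0.00701). The comparison took all masked sequence, not runs of other short repeats alone, and only summits of the thresholded list. Of the 144 peaks absent from that list, 89.6% were masked and 25 held an element. The strongest without an element (chromosome X, 15810958 to 15811173) had a signal of 2547. Whether runs of repeats draw peaks whatever their motif therefore stays open. Copy number stays open as well, since more copies in these worms than in the reference could raise the signal of an array. The rank correlation of signal with the number of elements (0.675) does not separate these accounts, and the peak lists hold no copy numbers. No biological explanation was tested, because the design has 1 group.

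Most promoter peaks, 1210 of 1338, lacked a perfect element. Elements with 1 changed base, sought here within 50 bp of the summit, do not account for them as a set, at 8.35% against 7.66% of matched windows (difference 0.690 percentage points, 95% interval -0.940 to 2.32). They may mark some of the strongest, since they were present at 25% of the 100 strongest of these peaks against 6.85% of the other 1110. At 23 such peaks of chaperone and chaperonin genes the share was 52.2%, above that of matched windows by 44.5 points (25.3 to 63.1). The lower bound fell short of the limit set, after the results were seen, for calling such elements the source of these 23 peaks. GC content alone as the whole source is argued against, because GCGCGC was 4.47 times as frequent as in unbound promoter windows of the same GC content (3.84 to 5.18), but only 14.5% of these peaks held it and their median GC content was 41.3% against 34.3% in unbound windows, so GC content stays open for the others. High transcription as a source stays open, since muscle, intestine and collagen genes were bound at 0.0812 times the share of ribosomal protein genes (0.0395 to 0.167) but no expression values show which of them were transcribed in these worms. A signal that any tagged protein would give at open promoters stays open too, and no biological explanation was tested.

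Some peaks passed the IDR threshold at very low signal, 96 of them below the median signal of the ranked list (24.4). Their promoter share was 38.5% (29.4 to 48.5), against 26.4% of 48835 peaks below the same signal that failed the threshold. The failed peaks were not matched on signal or on overlap with stronger peaks. The difference therefore cannot decide whether chance agreement gave these peaks. Of the 96, 50 overlapped a peak in the list of replicate 2 and 23 a peak in that of replicate 1. Of the 96, 25 lay in coding exons and 5 had a perfect element, so part of them could still be chance.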

How the results depend on the processing

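The 2 alternatives that leave out peaks in arrays or keep only peaks in both replicate lists were chosen after the data were seen. The replicate overlaps, the correlation, the promoter share, the heat shock element share and the share of the X chromosome kept their direction and passed their tests under every alternative run. The promoter share ranged from 33.3% (random 14.4%) with a window of 500 bp upstream to 62.0% (random 46.8%) with 2000 bp, the element share from 7.73% without arrays to 33.4% for peaks in both lists, and the X share from 5.34% to 8.18%. The number of lists bound more often, 14, fell to 9 in the stronger part of the pooled list and was 11 to 14 elsewhere. The number bound less often, 2, was 1 in the stronger part of the list, in the peaks of both replicate lists, with the nearest start only and with genes that share a summit counted once, and from 1 to 1 with either replicate left out, where the list lost was that of the sperm proteins. It was 3 in the conservative list and without arrays. With the shorter promoter window it stayed at 2, because the sperm call was lost (0%, exact adjusted p = 0.115) and the collagens newly passed. Of 339 alternatives for single lists, chromosomes and classes, 302 kept their side of the threshold, 30 fell short of it, 5 newly passed it and 2 counts without a test moved. Direction was compared only where both settings passed, and 0 of those reversed. A change of direction below the threshold was thus not counted as a reversal. The autophagy list, bound more often in the pooled list, was bound at 4% against 5.29% of other genes in replicate 2 alone. The cuticle collagens newly passed as bound less often in the conservative list (2.31%, exact adjusted p = 0.0186), with the shorter promoter window (0.578%, exact adjusted p = 0.00274) and without arrays (2.89%, exact adjusted p = 0.0291). These counts moved because arrays were left out: 37 of the 100 strongest peaks then had an element, against 78. Likewise, 12 large clusters, extended as above, overlapped a peak, against 262. In the stronger part of the pooled list the calls of the endoplasmic reticulum, autophagy, meiosis, mitochondrial and proteasome lists were lost, at 15.8%, 12%, 14.3%, 21.4% and 12.9% bound, and the share of other genes fell as well, from about 7.6% to about 4.7% for each list. The histone call was also lost with the shorter promoter window (9.72%, exact adjusted p = 0.165). The cause of these losses was not tested. A stricter IDR of 0.01 is the threshold the lists already have, so it changed nothing and gives no value. No paired analysis was possible because there is 1 group. The unknown depth limits what can be said of peaks that are absent from a list.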

Other observations

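The gene classes and regions described here were chosen after the data were seen. Among 175 classes of protein-coding genes that share a name and have at least 10 members, 6 were bound more often and 2 less often than other genes (two-sided Fisher's exact test, adjusted over the 175). Besides the ribosomal, histone, hsp and rpn genes, the rbm genes, which encode RNA-binding motif proteins, were bound more often, 5 of 13 (exact adjusted p = 0.0430). The C-type lectin genes (clec) were bound less often, 5 of 240 (2.08%, exact adjusted p = 0.00940), beside the str chemoreceptor genes, 1 of 193 (exact adjusted p = 0.000252). The nuclear pore genes (npp), 7 of 26, did not pass (exact adjusted p = 0.0522).

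Several strong promoter peaks lay at genes outside the fixed lists, and no shared function was tested among them. The peak at hcp-3, which encodes the centromeric histone (chromosome III, 9616945 to 9617288), ranked 12 with a signal of 4181. Peaks with 1 perfect element also lay at cls-2 and R107.5 (chromosome III, 9053824 to 9054269, signal 3070), at klp-7, a kinesin gene (chromosome III, 10807266 to 10807576, signal 2066), and at C16C10.13 and hrde-1, the latter of which encodes a nuclear Argonaute of the germline (chromosome III, 4176253 to 4176520, signal 1462).

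Peaks in element arrays lay mostly on chromosome arms, and the arm share of all genomic clusters was not counted. Of the 283 peaks with 6 or more elements, 88.7% (Wilson interval 84.5 to 91.9) lay on the arms of their chromosomes. The arms were taken as all that is outside a central part as long as each arm, so they cover most of each chromosome. The share was 65.4% for peaks with 1 to 5 elements. It was 56.6% (53.8 to 59.4) for promoter peaks without an element and 62.2% for protein-coding genes. Chromosomes IV and V held 78 and 73 of the 283 peaks. Inside genomic clusters of 6 or more elements, 75.6% of neighbouring elements started 5 bp apart, as in an uninterrupted run of GAA and TTC units, and 12% started 20 bp apart. The promoter summits with an element lay at a median of 259.5 bp upstream of the nearest transcript start, and those without at 192 bp.

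MicroRNA genes with a nearby summit included mir-51, mir-52, mir-53 and mir-54, with signals from 48.6 to 305.5, and none of the 12 bound microRNA genes had a perfect element at its summit. All 13 bound spliced leader genes were of the SL2 type, with signals from 64.6 to 254.8. The types of the unbound spliced leader genes were not counted, so a preference for the SL2 type was not tested.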
